A study of Homo sapiens with 5 samples.

How the data were processed

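The series measured where p63, a transcription factor of the p53 family that epidermal keratinocytes depend on, binds DNA in HaCaT cells, an immortalized human keratinocyte line. Binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody to p63. The labels describe 4 ChIP libraries and 1 input library. Cells were infected with an adenovirus carrying LacZ (the control gene), an active form of RAS (caRAS) or a dominant negative form (dnRAS). Per the labels' protocols, TGF-β3 was given at 3 ng/ml for 1.5 h, and the LacZ vector was also used without it. Each condition had 1 library, so no value has a replicate, no spread between samples can be given, and no p-value between conditions was computed. The expansions of caRAS and dnRAS are the usual ones and are not spelled out in the labels.

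Each ChIP library came with 1 deposited peak list, with chromosome, start, end, peak name and score. Peaks were called with MACS2 2.0.6 on hg18, per the submitters' processing notes. The aligner, read filters, use of the input and treatment of reads that match several places are not given in the sources used here, nor is whether runs were pooled. The deposited score was read as −log10 of a p-value, because no score lay below 5 in any of the 4 lists, as a threshold of 1e-05 would give. The lowest score was 5.23 in LacZ without TGF-β. It was 5.96, 5 and 5.87 in the lists labelled LacZ with TGF-β, caRAS and dnRAS. Only the list labelled caRAS thus reached 5, and the reading of the score is an assumption. Whether the score is from a p-value or a q-value is not stated. Scores are the authors' own values for each peak and were used to describe, rank or filter peaks within a list. Read depth is unknown for all libraries, because peak lists carry no read counts. A library with more reads yields more weak peaks, so the length of a list depends on depth and enrichment as well as on binding. The input library has no list of its own and was not analysed here.

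Groups were taken from the sample titles, and each list was taken for the sample under which it is deposited. For the 3 TGF-β libraries, the name of the deposited file states another arm than the label. The list labelled LacZ with TGF-β has a file name with caRAS, the list labelled caRAS one with dnRAS, and the list labelled dnRAS one with LacZ. All values below follow the labels, and the assignment by file name was computed as an alternative.

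Peaks of 2 lists were counted as shared when they overlapped by at least 1 bp. For each comparison the share of each list's peaks touched by the other list was computed in both directions, with a 95% Wilson interval. These intervals cover counting error over peaks only, not the spread between cultures. As a reference for chance, the second list was rotated within each chromosome 100 times. The rotation did not account for gaps in the assembly or for where DNA is open to binding. It is thus a reference for random placement only, and an overlap above it says nothing about the treatments. Overlapping peaks of the 4 lists were also merged to regions, and each region was described by the lists that hold a peak in it. Within each list, peaks were split into 4 bins of equal size by score. Positions are given on hg18, counted from 1.

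Before the data were examined, these alternatives were fixed: an overlap of at least 50% of both peaks, peaks within 500 bp counted as shared, a score of at least 10, the 5775 best-scored peaks of every list, and the assignment by file name. A score of at least 20 and the regions without the library labelled caRAS were added after seeing the data, as were the file name assignment for the peak counts and all counts over the 3 longer lists. Also fixed beforehand was the rule for regions named in the text. It takes the 5 best-scored peaks of each list, the 5 best-scored peaks of each list that the other list of a comparison does not touch, the 5 regions with the best mean score percentile in all 4 lists, and the widest peak of each list. Regions outside that rule are identified where they appear. Fixed gene lists for p63, p53, TGF-β, RAS, migration, differentiation and other cell types, and a motif search, were planned for an hg18 annotation and genome. The gene table at hand is on GRCh38, so peaks were not assigned to genes and no motif was searched.

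The overlap code was tested on simulated data: of 10160 peaks of the LacZ list without TGF-β, 7069 were made shared and 7069 were recovered. Shared peaks were moved by less than their width and the others far beyond every chromosome. Full recovery thus checks the counting only, not borderline overlaps. On random intervals its counts equalled those of bedtools 2.31.1. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.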

Results

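p63 binding regions were listed for HaCaT keratinocytes in 4 conditions, with 1 library each: LacZ vector without TGF-β, and LacZ, caRAS or dnRAS vector with TGF-β3 at 3 ng/ml for 1.5 h. The series asks how TGF-β and the state of RAS bear on where p63 binds. The authors' lists held 10160 peaks for LacZ without TGF-β, 10928 for the library labelled LacZ with TGF-β, 5775 for the library labelled caRAS and 10190 for the library labelled dnRAS. They covered 4.26, 5.16, 2.26 and 4.67 Mb of hg18. Median peak widths were 365, 385, 340 and 382 bp in the same order. Read depth is unknown, and there were no replicates, so each statement below compares libraries and not conditions.

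The labels of the 3 TGF-β lists disagree with the names of their files, and a strong peak near the start of chromosome 11 was held by just the 2 lists with RAS in the file name. A peak at chromosome 11, 522504 to 522918, had a score of 43.09 in the list labelled LacZ with TGF-β, whose file name states caRAS. The list labelled caRAS, whose file name states dnRAS, held it at 522505 to 522907 with a score of 80.8. The 2 lists with LacZ in the file name, labelled LacZ without TGF-β and dnRAS, held no peak there. All 4 lists held a strong peak ending between 525065 and 525243, which began at 524300 and 523958 in the 2 lists with LacZ in the file name. It began further left, at 523304 and 523306, in the lists labelled LacZ with TGF-β and caRAS. The first peak was picked because other lists lack it, so its match with the file names is no test of the labels. Over all regions, the 2 lists with RAS in the file name shared 35 regions held by no other list, the fewest of any pair. The 2 lists labelled caRAS and dnRAS shared 51, and LacZ without TGF-β and the list labelled caRAS 42. Pairs without the short list labelled caRAS shared 523, 606 and 739. Every pair with the short list was thus low, so these counts do not bear on the labels. Given the disagreement in names, libraries are called by their label throughout, and values under the file names are given beside each comparison.

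**Figure D1:**
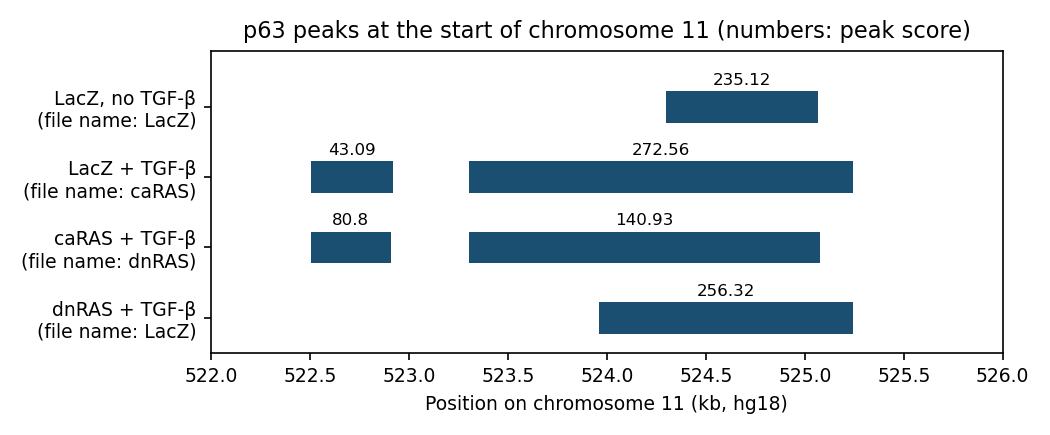
p63 peaks near the start of chromosome 11 (horizontal axis, kb on hg18) in the 4 lists (rows, with the label and the arm in the file name). Bars span the authors' peaks and the numbers are their scores; the left peak is present in the lists labelled LacZ with TGF-β (score 43.09) and caRAS (80.8) and absent from the other 2.

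The best-scored p63 sites of each list were held by all 4 libraries. The 4 lists merged to 13658 regions, of which 4957 (36.3%) held a peak in all 4 lists and 3773 (27.6%) in 1 list. The 5 best-scored peaks of each list fell into 9 distinct regions, and all 9 held a peak in all 4 lists. By mean score percentile the leading region lay on chromosome 17 at 4702774 to 4704559, with scores of 439.62, 434.58, 256.95 and 415.18 in LacZ without TGF-β and the libraries labelled LacZ with TGF-β, caRAS and dnRAS. It was followed by chromosome 9 at 138139023 to 138142393, chromosome 16 at 10595701 to 10596543, chromosome 20 at 48893801 to 48895434 and chromosome 17 at 35603267 to 35605356. The chromosome 9 site was also the widest peak of LacZ without TGF-β (2207 bp) and of the list labelled caRAS (2693 bp). In the list labelled LacZ with TGF-β the widest peak, of 3282 bp, lay on chromosome 6 at 157651330 to 157654611 with a score of 55.48. The widest peak of the list labelled dnRAS lay on chromosome 17 at 37063440 to 37066275 (2836 bp, score 102.36). Regions held by all 4 lists had a median best score of 50.44 and a median merged width of 670 bp. Taking the best score and merged span over 4 lists raises both against values from 1 list. In these regions the median span of peaks was 496 bp in LacZ without TGF-β. It was 588, 360 and 561 bp in the lists labelled LacZ with TGF-β, caRAS and dnRAS. Regions in LacZ without TGF-β alone had a median score of 11.4 and width of 234 bp, and those in the list labelled LacZ with TGF-β alone 10.8 and 236 bp. Regions in the list labelled caRAS alone had 9.94 and 218.5 bp, and those in the list labelled dnRAS alone 10.9 and 232 bp. Of the 264 peaks in the list labelled caRAS alone, 20 belonged to sets of equal width and score within 100 kb. Without the library labelled caRAS, 7605 regions were held by all 3 remaining lists.

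**Figure D2:**
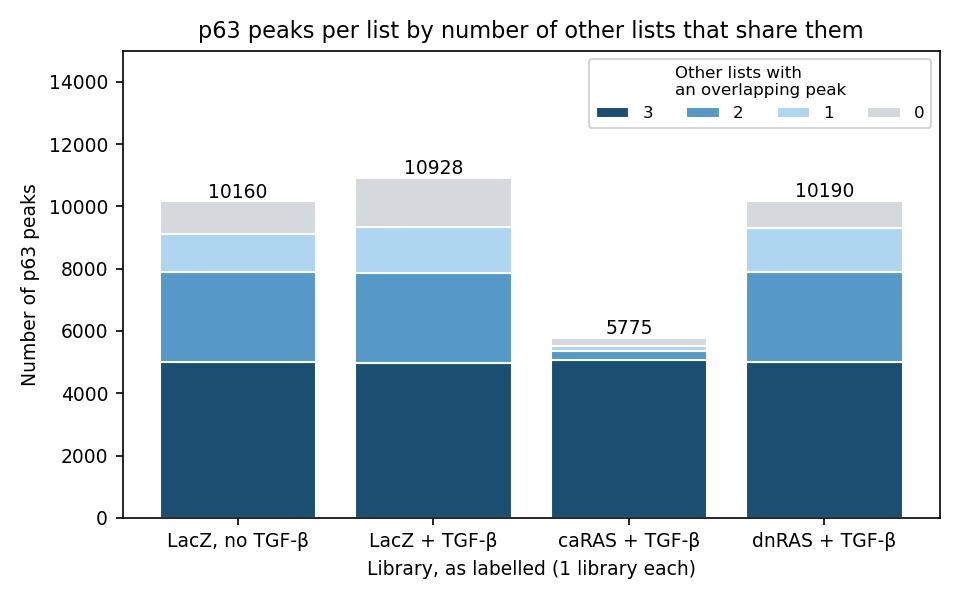
Number of p63 peaks in each authors' list (vertical axis) for the 4 libraries as labelled (horizontal axis), stacked by how many of the other 3 lists hold an overlapping peak. Peaks found in all 3 other lists numbered between 4982 and 5054 in each library, while the total ranged from 5775 to 10928.

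For the effect of TGF-β in LacZ cells, most p63 peaks were held both without and with TGF-β. Of the 10160 peaks without TGF-β, 8411 were touched by the list labelled LacZ with TGF-β (82.8%, 95% Wilson interval 82.0 to 83.5). In the other direction 8381 of 10928 peaks were touched (76.7%, 75.9 to 77.5). Rotated lists gave 0.349% and 0.344% on average. The best-scored peaks not touched by the list without TGF-β lay on chromosome 4 at 78341426 to 78341969 (score 55.02), chromosome 20 at 36263179 to 36263737 (53.26), chromosome 1 at 31677086 to 31677622 (52.53) and chromosome 18 at 40530927 to 40531287 (46.73). The fifth was the chromosome 11 interval described above. The chromosome 20 and chromosome 1 sites held peaks in all 3 TGF-β lists. The best-scored peaks of the list without TGF-β that were not touched lay on chromosome 20 at 6050696 to 6051180 (54.07), chromosome 1 at 181470030 to 181470720 (49.28) and chromosome 5 at 172453201 to 172453488 (36.65). The first 2 of these held peaks in the lists labelled caRAS and dnRAS, and the chromosome 5 site held none in any TGF-β list. Under the file names, the same comparison gave 82.3% and 81.9%.

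Whichever way the 3 TGF-β lists are assigned, 99 regions were held by all 3 of them and not without TGF-β. Besides the chromosome 20 and chromosome 1 sites above, the best-scored of the 99 lay on chromosome 6 at 149595711 to 149596385, with scores of 28.22, 19.41 and 41.64 in the lists labelled LacZ, caRAS and dnRAS, an example chosen after its values were seen. By the same count for another longer list, 113 regions lacked a peak only in the list labelled LacZ with TGF-β, and 74 only in the list labelled dnRAS. Among the 3 longer lists, both TGF-β lists shared 836 regions that were missing without TGF-β, against 636 missing in the list labelled LacZ with TGF-β and 680 missing in that labelled dnRAS. With the 10160 best-scored peaks of each of these 3 lists the counts were, in the same order, 746, 753 and 612, and with the 5775 best-scored they were 442, 415 and 350. With a score of at least 20 they were 405, 374 and 380. The count for the TGF-β pair was thus 1.23 times the next in the full lists, and it was the highest under each of these settings except the 10160 best-scored peaks, where it lay between the other 2. No test of the difference is possible with 1 library each.

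For active RAS, most sites of the list labelled caRAS were held in the list labelled LacZ with TGF-β, and fewer the other way round. Of its 5775 peaks, 5288 were touched (91.6%, 90.8 to 92.3), while it touched 5201 of the 10928 peaks labelled LacZ with TGF-β (47.6%, 46.7 to 48.5). Rotated lists gave 0.366% and 0.180%. The best-scored peaks missing from the list labelled caRAS lay on chromosome 9 at 20226495 to 20227194 (score 74.92) and 84158825 to 84159438 (66.63), chromosome 17 at 20805222 to 20805886 (74.06), chromosome 21 at 35816143 to 35816812 (68.27) and chromosome 2 at 231860674 to 231861050 (63.29). All 5 held peaks in both other lists. In the reverse direction the best-scored peak lay on chromosome 18 at 4500682 to 4501120 (35.22) and was in no other list. It was followed by chromosome 20 at 61710131 to 61710907 (32.53) and chromosome 17 at 36533305 to 36533716 (31.27), both of which held peaks in LacZ without TGF-β and in the list labelled dnRAS. With the 5775 best-scored peaks of each list, the shares were 77.3% and 75.4%. Under the file names the active RAS comparison gave 78.7% and 84.5% instead, and the short list became that of dnRAS.

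For dominant negative RAS, the list labelled dnRAS and the list labelled LacZ with TGF-β held most of each other's sites. Of 10190 peaks labelled dnRAS, 8606 were touched (84.5%, 83.7 to 85.1), and of 10928 labelled LacZ with TGF-β, 8600 (78.7%, 77.9 to 79.5). Rotated lists gave 0.371% and 0.343%. The best-scored dnRAS-labelled peaks outside the other list lay on chromosome 22 at 29016338 to 29017170 (40.15) and chromosome 5 at 114396344 to 114396714 (34.43), and both held peaks in the other 2 lists. The chromosome 11 interval led the peaks absent from the list labelled dnRAS. It was followed by chromosome 15 at 69878111 to 69878425 (42.39), also held without TGF-β, and chromosome 2 at 75680862 to 75681332 (40.71), held in no other list. Under the file names this comparison gave 92.5% of the dnRAS peaks and 51.6% of the LacZ peaks.

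Between the RAS arms, 5342 of the 5775 peaks labelled caRAS were touched by the list labelled dnRAS (92.5%, 91.8 to 93.2), and 5262 of 10190 in the other direction (51.6%, 50.7 to 52.6). Rotated lists gave 0.337% and 0.191%. The best-scored dnRAS-labelled sites missing from the list labelled caRAS lay on chromosome 2 at 156530219 to 156530642 (78.81), chromosome 9 at 20226643 to 20227083 (73.02) and chromosome 2 at 235255849 to 235256550 (63.59). All 3 also held peaks in both LacZ-labelled lists. Apart from the chromosome 11 and chromosome 18 sites, the caRAS-labelled peaks missing from the list labelled dnRAS scored at most 32.53, on chromosome 8 at 139287568 to 139288335. Under the file names the shares were 47.6% of caRAS peaks and 91.6% of dnRAS peaks.

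Sharing rose with the peak score in each list. In the lowest of 4 equal-sized score bins, 67.8% of peaks of LacZ without TGF-β had an overlapping peak in any other list. The values were 58.7%, 86.1% and 73.4% for the lists labelled LacZ with TGF-β, caRAS and dnRAS. In the top bin these shares were 100%, 99.96%, 99.93% and 100%. The list labelled caRAS held 10.8% (9.65 to 11.98) of the lowest bin of peaks labelled LacZ with TGF-β, 24.2% and 59.7% of the next 2 bins, and 95.7% (94.9 to 96.4) of the top bin. The list labelled dnRAS held 44.5%, 74.3%, 96.0% and 99.9% of the same bins. Of 2020 regions in the top bin of each of the 3 longer lists, 20 lacked a peak in the list labelled caRAS (0.99%, 0.64 to 1.52).

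**Figure D3:**
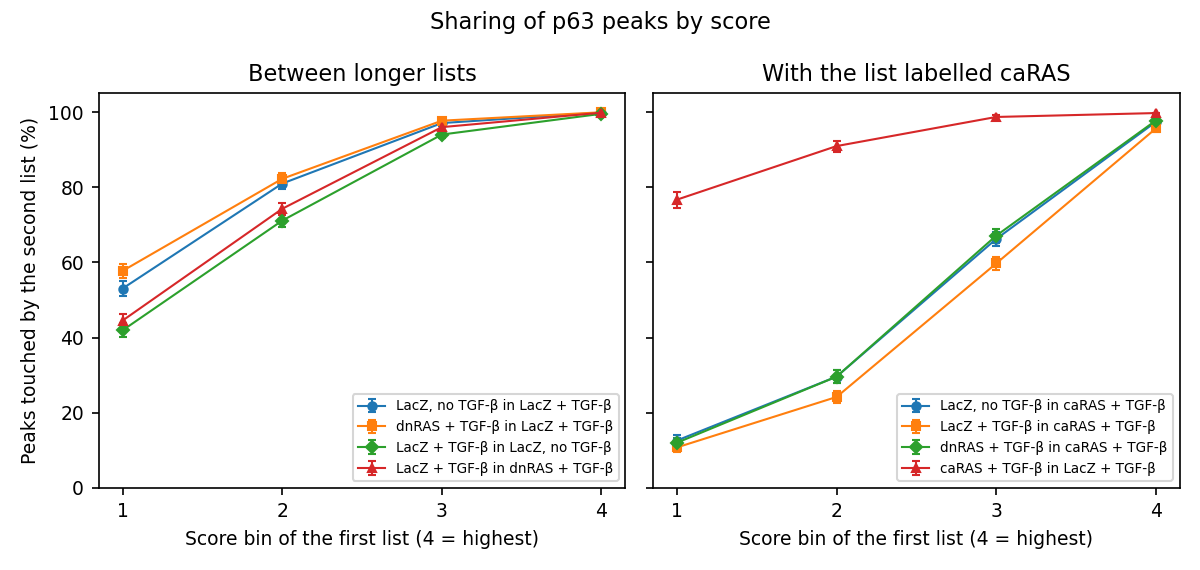
Percent of peaks of the first-named list touched by the second-named list (vertical axis) in each of 4 equal-sized score bins of the first list (horizontal axis, 4 is highest), with libraries as labelled; bars are 95% Wilson intervals for counting error. Longer lists held 41.9 to 57.8% of each other's lowest bin (left), while the list labelled caRAS held 10.8% of the lowest and 95.7% of the top bin of LacZ with TGF-β (right).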

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

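The 4957 regions held by all 4 lists numbered 3881 to 4924, within 1.5 times, under the score of at least 10, the 500 bp and the 5775-peak alternatives. Assignment by file name cannot change this number. With an overlap of at least 50%, peaks of the list labelled caRAS were counted and not regions. Of these, 3419 had a partner in each other list, against 5054 at 1 bp. The regions numbered 2445 with a score of at least 20 and 7605 without the library labelled caRAS, both chosen after seeing the data. Taking the lists by file name made 10928 peaks the caRAS list and 5775 the dnRAS list, and gave 81.9% of LacZ TGF-β peaks touched by the list without TGF-β. It also gave 78.7% and 84.5% for active RAS, 92.5% and 51.6% for dominant negative RAS, and 47.6% and 91.6% between RAS arms, because the lists trade places. The following values are given as the share of the first and then of the second list, for TGF-β, active RAS, dominant negative RAS and between RAS arms. With an overlap of at least 50% of both peaks they were 76.5% and 71.1%, 69.1% and 36.5%, 78.8% and 73.5%, and 75.7% and 42.9%. That setting also gave 60.5%, 49.6%, 72.3% and 63.8% for sharing of the lowest score bin, and 99.8%, 99.3% and 98.4% for the top bin of the first 3 lists. With peaks within 500 bp counted as shared, the shares that moved were 80.5% of LacZ TGF-β peaks in the TGF-β comparison, 51.0% of LacZ peaks held by caRAS, 85.8% and 81.9% for dominant negative RAS, and 53.8% of dnRAS peaks held by caRAS. A score of at least 10 gave 84.2% and 78.7%, 93.6% of caRAS peaks, 85.5% and 80.5%, and 94.2% of caRAS peaks. A score of at least 20 left 5599, 5575, 2567 and 5491 peaks and gave 83.5% of LacZ TGF-β peaks, 97.9% and 44.9%, 85.4% and 84.0%, and 98.4% and 45.9%. With 5775 peaks from each list the values that moved were 83.2% of LacZ TGF-β peaks, 77.3% and 75.4%, 84.8% of LacZ peaks held by dnRAS, and 79.1% and 77.4%; here list length no longer differs. The cause of the other moves was not tested. The planned gene lists and motifs were not run, since no hg18 annotation or genome was used here. With 1 library per condition no replicate could be left out. No paired analysis was possible because each group has 1 library. Read depth, on which the number of weak peaks in a list depends along with enrichment and binding, is unknown.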

Other observations

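Tests in this part were chosen after the results were seen, except the overlap of equally long lists. p63 regions were unevenly spread over the genome. Per Mb between its first and last peak, chromosome 22 held 9.37 regions, chromosome 17 held 9.32 and chromosome 20 held 8.12, against 2.39 on chromosome 4 and 2.67 on chromosome X. Chromosome 20 also had the highest share of regions held by all 4 lists (43.4%, 39.1 to 47.7) and chromosome 13 the lowest (28.5%, 23.4 to 34.3). Regions lay near each other more often than regions placed at random on the same chromosome. Of the 4957 regions held by all 4 lists, 603 had another such region within 10 kb (12.2%, 11.3 to 13.1), against 3.95% on average and at most 4.94% in 100 random placements. The random placements did not account for gaps in the assembly or for gene density. Among 100 kb windows, chromosome 8 from 43900001 to 44000000 held 20 regions, chromosome 17 from 35900001 to 36000000 held 17, chromosome 17 from 22100001 to 22200000 held 15 and chromosome 6 from 30800001 to 30900000 held 14, with peaks of all 4 lists in each. The first of these and another on chromosome 8, from 46900001 to 47000000 with 13 regions, border the longest stretch without peaks on that chromosome (3.00 Mb). General knowledge of hg18 places the centromere gap there, and places that of chromosome 17 next to the window with 15 regions. Windows on chromosome 1 from 141800001 (10 regions) and 142300001 (11) follow a stretch without peaks of 20.4 Mb. Reads from repeats are not excluded in such windows, so their counts do not show clustered p63 sites. Without all windows of 9 or more regions, 552 of 4884 regions held by all 4 lists had a neighbour within 10 kb (11.3%, 10.4 to 12.2), against at most 4.75% in random placements.

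The peak lists of the TGF-β libraries may be attached to other samples than the labels say. The peak at 522504 to 522918 of chromosome 11 was held by just the 2 lists with RAS in the file name, but it was noticed among the best-scored peaks that another list lacks, so this match alone tests nothing. Of 2 regions in the top score bin of exactly 2 lists and absent from the others, 1 was this peak. The other, on chromosome 2 at 69599491 to 69599843, was held by the lists labelled LacZ with TGF-β and dnRAS. These are not the 2 RAS arms under either assignment, so that region does not bear on the labels. With the picked peak the only other such region, the question stays open. This peak lay at score percentiles of 77.4 and 96.3 in its lists, but it was picked among the best-scored peaks that another list lacks. Its high score is therefore no test of whether peaks differ at random. Of 1382 regions in the top bin of both lists, this one included, 2 lacked a peak in either other list (0.14%, 0.04 to 0.53). That rate does not bear on a peak picked as an exception, so random differences stay open. Rare loss of a strong peak is not excluded. Both lists also extended the neighbouring peak by at least 652 bp. Among 4957 shared regions, it was the only extension of 500 bp or more confined to this pair, but it was examined because of the picked peak beside it. Such extensions were also confined to the lists labelled LacZ with TGF-β and dnRAS in 12 regions, and to LacZ without TGF-β and labelled caRAS in 1. The extension alone thus does not set the pair apart. General knowledge of hg18 places HRAS at this interval, though no hg18 annotation was used here and the labels do not say which RAS gene the vectors carry, so DNA of the RAS vectors is a candidate source. p63 binding in RAS-infected cells cannot be told apart from it without reads, and neither tells which of the 2 lists is caRAS and which dnRAS. Both sources presume the assignment by file name, since under the labels 1 of the 2 lists is LacZ.

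The shorter list labelled caRAS may reflect a library in which weak sites did not reach the caller's threshold, whichever arm it belongs to. The share of LacZ TGF-β peaks that it held was 84.9 percentage points higher in the top score bin than in the lowest, but the longer lists without TGF-β and labelled dnRAS also gave 57.7 and 55.3 points, so this does not decide. For regions in the top bin of each of the other 3 lists, loss of a sizeable set is argued against, since 0.99% lacked a peak. This covers only sites strong in all 3. At any score, 2646 regions were held by the 3 longer lists and not by the list labelled caRAS. Of these, 1665 had a best score of at least 20. Regions held by all 4 lists numbered 4957, of which 4686 had such a score. Of the top bin of LacZ TGF-β peaks alone, the list labelled caRAS held 95.7% and the list labelled dnRAS 99.9%. Strong peaks of 1 list were thus missing more often in the list labelled caRAS. Lower p63 occupancy at all sites in the library of the list labelled caRAS stays open too. With equally long lists 75.4% of LacZ TGF-β peaks were touched, and fewer reads and lower occupancy predict the same, so they cannot be told apart from peak lists.

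A row of 17 peaks on chromosome X, 114867129 to 114913946, was in the list labelled caRAS, while the list labelled LacZ with TGF-β held 1 peak there and the other 2 lists none. Of the 17, 15 had the same width of 215 bp and the same score of 17.51 (88.2%), as the same reads placed on each copy of a tandem repeat would give. Of the 14 gaps between these 15 peaks, 13 were 2969 to 3009 bp long, a range of 1.34% of the median spacing, and the remaining 1, of 7792 bp, held the 2 other peaks. This regularity, with the equal scores, argues against separate p63 sites. Peaks of equal width and score, 3 or more within 100 kb, numbered 21 in that list and 0 in the others, and made up 20 of the 264 peaks that it alone held. How reads with several matches were treated is not given in the sources used here.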
